A study of Mus musculus with 7 samples.

How the data were processed

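The series measures single-nucleus RNA expression in whole ileum of SAMP1/YitFc and AKR/J mice at 20 weeks of age. Per the labels, the ileum was flushed with PBS and snap frozen, nuclei were isolated with a CitraPrep kit and an iodixanol gradient, and polyA RNA was sequenced. The authors processed reads with Cell Ranger 7.2.0 against mm10 and used Seurat; the deposited matrices hold UMI counts per barcode for 32285 genes. The annotation, the intron setting and the threshold for calling cells are not stated. The labels list 7 samples, of which 6 libraries were analysed, 2 AKR (1 female, 1 male) and 4 SAMP (2 female, 2 male); AKR replicate 3 was not analysed here. Each library is 1 mouse, and libraries are the unit of every test. The labels do not tie a replicate number to a batch or animal shared by the strains. The file names carry 4 prefixes, 2 of which hold a library of each strain; the labels do not say what a prefix means, so it was used as an alternative block and to compare libraries within a prefix.

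Nuclei were kept with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs. Doublets were removed with Scrublet in each library at its automatic threshold or, where that marked under 0.5% of nuclei, as the top share by score at 0.8% per 1000 nuclei. This removed 23.8% and 15.4% of nuclei in AKR 1 and AKR 2 and 11.1%, 10.6%, 2.56% and 7.77% in SAMP 1 to SAMP 4; the automatic threshold was used in AKR 1, AKR 2 and SAMP 3. Clustering used scanpy 1.11.5 with 3000 variable genes chosen within libraries, 50 principal components, 20 neighbours and the Leiden algorithm in igraph 0.11.9 at resolution 2 with seed 1, without integration, and gave 48 clusters. Clusters were named from 27 marker lists by a score, the mean of each marker's level relative to its highest cluster times the share of markers detected, where detected means in at least 10% of nuclei and over 2-fold above the lower quartile of clusters. A cluster was left unnamed with fewer than 3 markers or under 50% of the list detected, with median UMIs over 2 times those of its libraries, with another class scoring over 0.85 of the best, with more markers of another class than of its own among its top 10 genes, or with no own marker there and over 1.5 times as many markers of another class detected. These thresholds were set after the clusters were seen. This gave 16 named classes, with macrophage and dendritic, and enteric neuron and glia, joined where markers of both led.

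Counts were summed per library over all kept nuclei (whole tissue) and over the nuclei of each class. A class was tested where both AKR and at least 3 SAMP libraries held at least 20 nuclei, which 11 classes met. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood) in R 4.3.3 with strain as the only term and Benjamini-Hochberg adjustment, at an adjusted p under 0.05. Standard errors of log2 differences are the absolute log2 difference over the square root of F, and CPM values are normalised with TMM. Class shares were compared with an exact permutation test of the difference of means over 15 arrangements. Females and males were compared with strain as a covariate, and the strain by sex interaction was tested in the same way. Gene coordinates are those of GENCODE vM21 on mm10.

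Of 27 gene lists with 472 genes, each was tested in whole tissue and in its home classes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of the same sums, and again with an estimated correlation. The lists were collagen and matrix, inflammatory stroma, stromal niche signals, muscle contraction, synthetic muscle, enteric transmitters, reactive glia, MHC class II, interferon response, epithelial defence, type 2 immunity, type 1 and 17 immunity, lymphoid follicle, lymphatic growth, goblet and mucin, Paneth products, bile acid handling, lipid absorption, sugar and peptide absorption, villus tip, crypt stem, proliferation, regenerative epithelium, gastric gland, unfolded protein response, handling stress and circadian clock. Members were also adjusted over each list alone. The genes named in whole tissue are the 10 higher and 10 lower with the largest log2 difference among called genes with a mean log2 CPM of at least 3, all SAMP libraries on the same side of both AKR libraries and no predicted or clone name. Each class names 5 higher and 5 lower at a mean log2 CPM of at least 5, leaving out genes under 10% of their level in the highest class, and each list up to 4 members with the smallest p, not all of which are printed. A gene that this rule picks is not reported here. Groups, tests, lists, marker genes, the filters on nuclei and this rule were set before the data were examined.

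With changes added to simulated data, edgeR recovered 79.3% of genes changed by a log2 of 2 and 11.7% of those changed by 1 in whole tissue, 62.0% and 10.5% in enterocytes, and 25.3% and 3.41% in plasma nuclei. Alternatives were DESeq2 1.42.0, other size factors, no low-count filter, sex as a covariate, and the replicate number within sex or the file prefix as a block. Others were doublets kept, at least 1000 UMIs, thinning to the smallest library and equal class makeup. Genes scaled within libraries before clustering (44 clusters), other camera settings and leaving out each library were also used. Equal class makeup weighted the 11 tested classes alike in every library, left out all other nuclei and tested log2(CPM + 1) with limma, without TMM. A uniform doublet share, leaving out ribosomal RNA-like genes, a UMI minimum without those genes and counting unnamed clusters as enterocytes or as Paneth nuclei were added after the data were seen. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.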

Results

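Single-nucleus RNA sequencing was carried out on whole ileum of 20-week-old SAMP1/YitFc mice, an inbred strain that develops ileitis spontaneously, and of AKR/J mice, its usual control strain. The question was how the ileum of SAMP1/YitFc mice is remodelled during chronic ileitis. The only contrast was between the strains at this age. Ileitis therefore cannot be told apart from other strain differences, including in how reads map to mm10. Count matrices of 2 AKR/J libraries (AKR 1, female; AKR 2, male) and 4 SAMP1/YitFc libraries (SAMP 1 and SAMP 2, female; SAMP 3 and SAMP 4, male) were compared, each from 1 mouse. AKR replicate 3 was not analysed here. Total UMI counts were 72228385 and 64435965 in AKR 1 and AKR 2, and 58853605, 42360774, 80164098 and 76221861 in SAMP 1 to SAMP 4. The 6 libraries held 72912 barcodes, of which 50863 nuclei were kept, with 10096 and 7520 from the AKR libraries and 6924, 7510, 10056 and 8757 from the SAMP libraries. The median nucleus kept had 3266 and 4559 UMIs in AKR and 4276, 3013, 4530 and 4798 UMIs in SAMP. A single transcript, Gm42418, which overlaps ribosomal RNA sequence on chromosome 17 (mm10, 39846958 to 39848788), held 2.09% and 3.14% of all UMIs in AKR 1 and AKR 2, but 22.4%, 21.9%, 19.7% and 18.5% in SAMP 1 to SAMP 4. This difference between the strains runs through every comparison below.

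The nuclei fell into 16 classes named from marker genes, and each name below stands for nuclei that are like that cell type. SAMP ileum held fewer enterocytes, the absorptive cells of the villus, at 42.7% ± 9.06 of nuclei (SD, n = 4) against 67.6% ± 5.31 (SD, n = 2) in AKR ileum, and all 4 SAMP libraries lay below both AKR libraries. Tuft nuclei, the chemosensory cells that release interleukin 25, made up 4.48% ± 0.904 of nuclei in SAMP and 0.120% ± 0.169 in AKR. Paneth nuclei, the defensin-secreting cells of the crypt base, made up 9.33% ± 1.16 in SAMP and 1.65% ± 0.414 in AKR, a difference that depended on an AKR cluster led by Defa21 and Defa22 that was left unnamed. Smooth muscle nuclei were at 4.25% ± 0.888 against 2.20% ± 0.0623. Lymphatic endothelial nuclei were at 0.428% ± 0.132 against 0.0797% ± 0.0566, and enteroendocrine nuclei at 0.712% ± 0.0638 against 0.226% ± 0.320. For these 6 classes every SAMP library lay outside both AKR libraries, which gave p = 0.0667 in a 2-sided exact permutation test, the smallest p that 15 arrangements allow (adjusted p = 0.178 over the classes). With an edgeR quasi-likelihood test of the nuclei counts, the adjusted p was 0.00483 for Paneth (log2 difference 2.50), 0.0309 for tuft (5.27) and 0.0309 for lymphatic endothelial nuclei (2.45). It was 0.114 for smooth muscle nuclei, 0.188 for enterocytes and 0.410 for enteroendocrine nuclei.

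For 4 of these 6 classes, all but tuft and enteroendocrine nuclei, the exact permutation p rose above 0.0667 under another way of counting. The unnamed cluster led by Defa21 scored alike for Paneth and crypt progenitor markers and held 6.46% of AKR and 0.268% of SAMP nuclei. Counted as Paneth, it brought that class to 9.60% in SAMP and 8.11% in AKR (exact permutation p = 0.4; edgeR adjusted p = 0.582, log2 difference 0.24). With genes scaled within each library before clustering, Paneth nuclei were at 5.51% and 4.20% (exact permutation p = 0.333), and SAMP 1 lay below both AKR libraries. Smooth muscle nuclei were then at 6.075% and 4.41% (exact permutation p = 0.333), with SAMP 1 below AKR 2. As a share of named nuclei outside the epithelium, smooth muscle was at 25.1% and 19.7% (exact permutation p = 0.467). With doublets kept it was at 4.60% and 3.01% (exact permutation p = 0.133). Lymphatic endothelial nuclei were at 0.439% and 0.175% with doublets kept, and only 3 SAMP libraries lay above both AKR libraries there and with a uniform doublet share (exact permutation p = 0.200 in both). Enteroendocrine nuclei were at 0.740% and 0.508% with doublets kept, a ratio of 1.46 instead of 3.15, and AKR 1 then held 72 of them instead of 0. With unnamed SAMP epithelial clusters counted as enterocytes, except a cluster left unnamed for its high UMIs, enterocytes were at 52.65% in SAMP and 67.65% in AKR (exact permutation p = 0.133). The excepted cluster scored best for enterocyte markers. It held 4.78% of SAMP nuclei on average (8.31% in SAMP 4) and 0.0116% of AKR nuclei, so counting it would narrow the difference further.

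**Figure D1:**
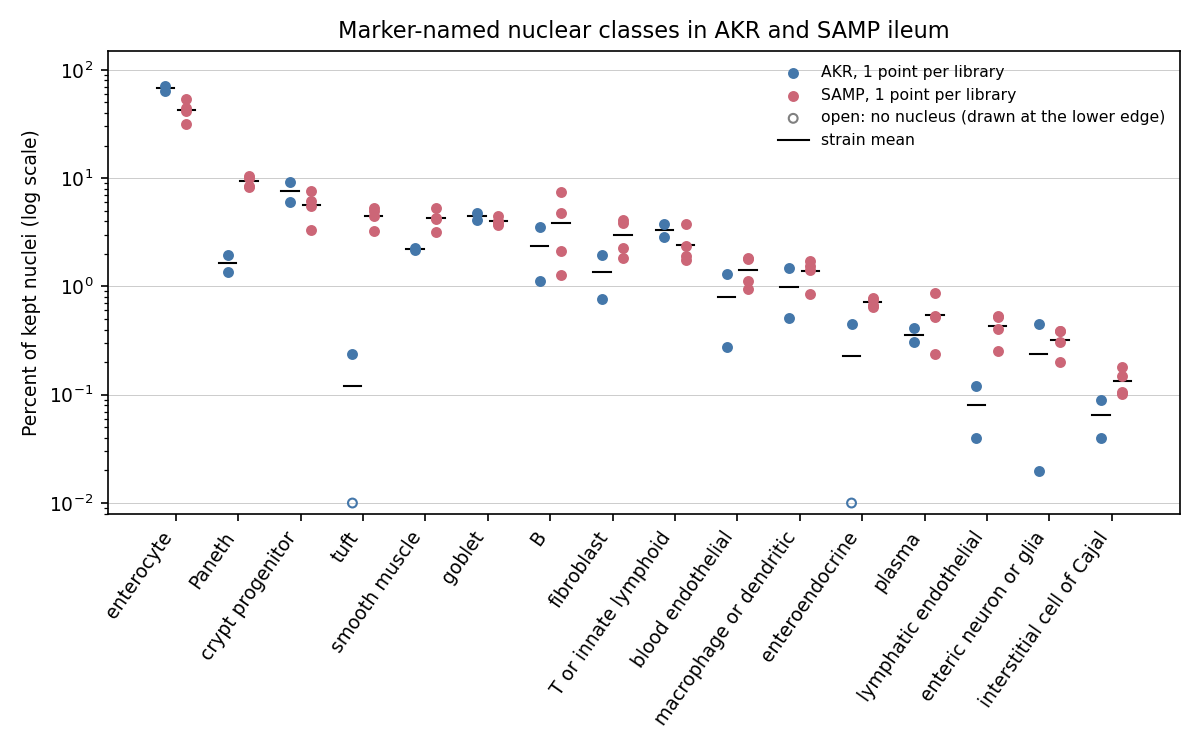
Percent of kept nuclei in each class on a log axis, with 1 point per library (2 AKR, 4 SAMP) and a bar at each strain mean; open points at the lower edge stand for libraries with no nucleus of the class. The SAMP libraries sit above both AKR libraries for the Paneth, tuft, smooth muscle, lymphatic endothelial and enteroendocrine classes, and below both for enterocytes.

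For the other classes the exact permutation test did not reach its smallest p. Interstitial cells of Cajal lay above both AKR libraries in all 4 SAMP libraries, at 0.134% ± 0.0368 against 0.0645% ± 0.0348 (exact permutation p = 0.133), but were at 0.136% and 0.149% with doublets kept. Crypt progenitors were at 5.63% ± 1.77 in SAMP and 7.61% ± 2.34 in AKR (exact permutation p = 0.4). Goblet nuclei were at 4.00% ± 0.330 and 4.42% ± 0.457 (exact permutation p = 0.267), fibroblasts at 3.01% ± 1.14 and 1.36% ± 0.827 (exact permutation p = 0.200). T or innate lymphoid nuclei were at 2.44% ± 0.912 and 3.31% ± 0.680 (exact permutation p = 0.333), and B nuclei at 3.89% ± 2.78 and 2.35% ± 1.72 (exact permutation p = 0.467). Goblet nuclei lay below both AKR libraries in all 4 SAMP libraries with doublets kept, at 3.98% and 5.33%, and so did T or innate lymphoid nuclei as a share of named nuclei outside the epithelium, at 13.6% and 30.7% (exact permutation p = 0.0667 for each). Within the T or innate lymphoid class, a cluster led by Cd8a, the coreceptor of cytotoxic T cells, was at 0.661% ± 0.275 in SAMP and 2.51% ± 0.974 in AKR (exact permutation p = 0.0667, the smallest possible). A crypt cluster led by the cycling genes Top2a, Cenpf and Mki67 was at 2.64% ± 0.650 and 4.57% ± 1.47 (exact permutation p = 0.0667), while the crypt cluster led by Lgr5, the stem cell receptor, was at 2.99% ± 1.36 and 3.05% ± 0.870 (exact permutation p = 1). Nuclei in clusters that no marker list named made up 15.3% in SAMP and 6.58% in AKR on average. Clustering bore on these shares, since enterocytes of the strains formed almost wholly separate clusters, and 93.3% of AKR Paneth nuclei sat in a cluster with no SAMP nucleus. With genes scaled within each library before clustering, goblet nuclei were at 7.61% in SAMP and 4.71% in AKR (exact permutation p = 0.0667), tuft nuclei at 4.39% and 0.133%, and enterocytes at 30.6% and 66.2%. This left 1896, 2259, 1946 and 2676 nuclei of SAMP 1 to SAMP 4 unnamed, against 25 and 319 of AKR 1 and AKR 2. An unnamed cluster that scored best for enterocyte markers held 15.4%, 18.0%, 0.825% and 15.6% of SAMP 1 to SAMP 4. The enterocyte gap under this setting therefore depends in part on naming.

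Tuft nuclei were then counted without clustering, at a fixed depth of 1000 UMIs per nucleus. Nuclei with at least 2 of 9 tuft marker genes, among them Dclk1, Trpm5 and Pou2f3, made up 5.57%, 5.12%, 4.44% and 3.36% of nuclei in SAMP 1 to SAMP 4 and 0.0207% and 0.333% in AKR 1 and AKR 2. Enterocytes, which should lack these genes, passed the same count at 0% to 0.236%. In the cluster-based count AKR 1 held 0 of 10096 nuclei, which allows a share of up to 0.0297%, and AKR 2 held 18 of 7520, or 0.239% (95% Wilson interval 0.151% to 0.378%). With doublets kept AKR 1 held 22 tuft nuclei, or 0.166%, and with a uniform doublet share 21, or 0.179%, so its count of 0 depended on doublet removal. SAMP 3, which shares its file name prefix with AKR 1, held 4.43% (4.04% to 4.84%), and SAMP 4, which shares that of AKR 2, held 3.24% (2.89% to 3.64%).

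**Figure D2:**
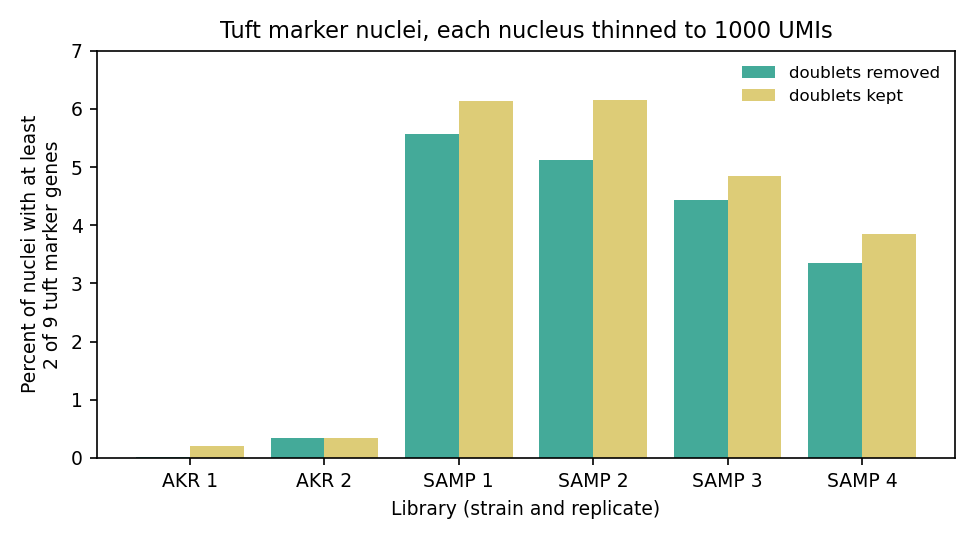
Percent of nuclei with at least 2 of 9 tuft marker genes after each nucleus was thinned to 1000 UMIs, as 1 bar per library with doublets removed and 1 with doublets kept. With doublets kept, the 4 SAMP libraries lie between 3.86% and 6.15% and the 2 AKR libraries at 0.204% and 0.338%.

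Summed over all nuclei of a library, the genes with the largest differences included Ppef1, Vmn2r26 and Galnt14 on the higher side. On the lower side they included 4 alpha-defensins and Klrb1. Pla2g4c, a cytosolic phospholipase A2 (ENSMUSG00000033847; mm10 chromosome 7, 13324655 to 13360672), was at 1690 ± 395 CPM (SD, n = 4) in SAMP and 15.2 ± 0.445 (SD, n = 2) in AKR, a log2 difference of 6.80 ± 0.37 (SE). Ppef1 (log2 7.84 ± 0.49), Vmn2r26 (7.81 ± 0.92), Galnt14 (7.81 ± 0.57) and Triml2 (7.10 ± 0.66) were also higher. The others on this side were Frmpd4 (6.82 ± 0.64), the potassium channel Kcnj16 (6.66 ± 0.33), the sialyltransferase St3gal4 (6.54 ± 0.53) and the gasdermin Gsdmc3 (6.42 ± 0.49). On the lower side, Defa21, an alpha-defensin (ENSMUSG00000074447; chromosome 8, 21025545 to 21026516), was at 1.07 ± 0.771 CPM against 689 ± 425 (log2 -9.40 ± 0.66). Klrb1, a lectin-like receptor of killer cells (ENSMUSG00000079299; chromosome 6, 128705836 to 128723059), was at 0.544 ± 0.280 against 40.6 ± 14.5 (log2 -6.30 ± 0.42). It was among the top 10 genes of AKR enterocyte clusters and of no lymphoid cluster, so its difference is no measure of killer cells. Also lower were Defa22 (-5.67 ± 0.59), Defa36 (-5.54 ± 0.51), Clca3a2 (-4.18 ± 0.35) and Gal3st2 (-3.94 ± 0.38). Defa29 (-3.79 ± 0.72), Akr1b7 (-3.63 ± 0.44), Pard3bos1 (-3.62 ± 0.27) and Prss48 (-3.57 ± 0.29) were also lower. The Defa and Gsdmc families hold close paralogs and Pard3bos1 is an antisense transcript, so the assignment of their reads to a single gene is uncertain.

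**Figure D3:**
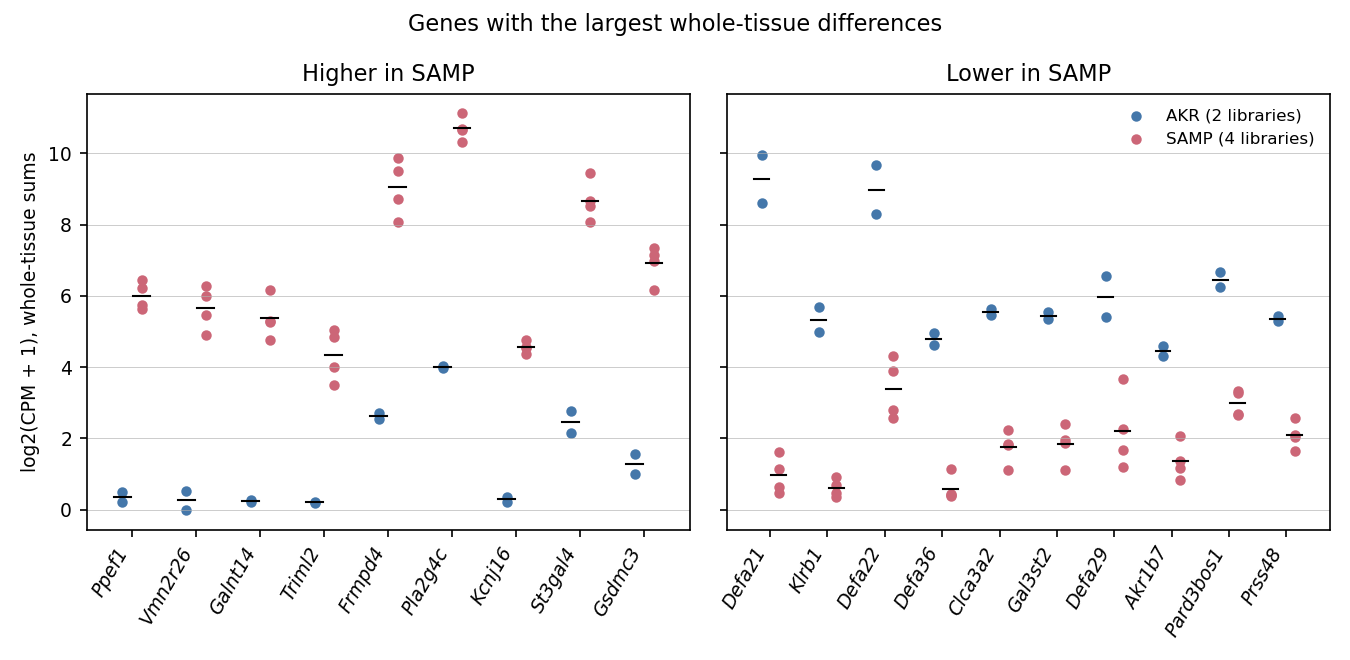
Expression of the 19 genes named above as log2(CPM + 1) of whole-tissue sums, with 1 point per library (2 AKR, 4 SAMP) and a bar at each strain mean. For each gene the 4 SAMP libraries lie on the same side of both AKR libraries.

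In total 5314 of 18934 genes differed between the strains at an adjusted p under 0.05 (edgeR quasi-likelihood, Benjamini-Hochberg), 2152 higher and 3162 lower in SAMP. With equal class makeup, which leaves out nuclei outside the 11 tested classes, 789 genes were higher and 7482 lower. The median log2 shift over all genes was -0.38. Frmpd4, a leading gene of the tuft cluster, lost its call (log2 0.24), but tuft nuclei were among those left out. With the file name prefix as a block, which leaves 1 residual degree of freedom, 488 genes passed, 196 higher and 292 lower, of which 486 were called in the same direction without it. Without AKR 1, 2817 genes passed. The 19 genes named above kept their calls in both of these.

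The gene lists fixed before the data were examined moved in both directions, and 5 of the 26 measured in whole tissue passed camera's test against the other genes. No list kept its call in whole tissue when camera estimated the correlation between genes. For MHC class II the estimate was 0.000336, below the preset 0.01, so a correlation above the preset is not what removed that call. In the list of type 2 immunity, the response to worms and allergens, 9 of 19 measured members were higher and 0 lower, and 13 were higher adjusted over the list alone. Il1rl1, the receptor of interleukin 33, was at 58.8 ± 23.6 CPM in SAMP and 2.22 ± 2.19 in AKR (log2 4.72 ± 0.72). The eosinophil receptor Ccr3 (log2 5.34 ± 0.96) and the goblet cell product Retnlb (log2 4.25 ± 0.87) were also higher, and Retnla was at 1.24 ± 0.645 CPM against 0.0176 ± 0.0249. The list passed camera upward (adjusted p = 0.000119; adjusted p = 0.358 with an estimated correlation). MHC class II genes, which present antigen to helper T cells, were lower for 6 of 11 members, with the same 6 adjusted over the list alone, and passed camera downward (adjusted p = 0.0105; adjusted p = 0.358 with an estimated correlation). Cd74, the invariant chain, was at 132 ± 22.1 CPM against 475 ± 64.3 (log2 -1.85 ± 0.20), H2-Aa at log2 -1.69 ± 0.28 and H2-DMa at log2 -1.35 ± 0.16. H2 genes vary in sequence between mouse strains, and an effect of this on mapping to mm10 was not tested.

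The proliferation list was lower for 10 of 28 members and for 15 adjusted over the list alone, with Pcna, the polymerase clamp, at log2 -1.18 ± 0.21, the mitotic kinase Plk1 at -1.66 ± 0.33 and the cyclin Ccnb1 at -1.50 ± 0.31 (camera adjusted p = 0.000119; adjusted p = 0.865 with an estimated correlation). In the list of collagen and matrix, 1 of 31 members was higher, Fn1, which encodes fibronectin (89.5 ± 22.7 CPM against 16.3 ± 2.34; log2 2.45 ± 0.28), and 1 adjusted over the list alone. That list passed camera upward (adjusted p = 0.0150; adjusted p = 0.865 with an estimated correlation), but not without AKR 1 (adjusted p = 0.843). In its home classes, fibroblast and smooth muscle, the median of collagen and matrix was log2 -0.31 and -0.13 (camera adjusted p = 0.116 and 0.594). The upward direction in whole tissue was therefore not seen within these classes. The regenerative epithelium list was higher for 4 of 13 members, and adjusted over the list alone for 5 higher and 1 lower. Of the 4, Ccn1 lost its call without SAMP 1 or SAMP 2 (edgeR adjusted p = 0.0508 and 0.0502) and Areg without SAMP 2 (0.0526). Ccn1 and Areg also lost their calls without AKR 1 (log2 1.70 and 1.05) and without AKR 2 (log2 1.65 and 1.28). Basp1 was at log2 3.42 ± 0.60 and Cd44, the hyaluronan receptor, at 1.16 ± 0.29, a call that Cd44 lost without AKR 1 (adjusted p = 0.119) and Basp1 with equal class makeup. That list passed camera upward (adjusted p = 0.0438; adjusted p = 0.865 with an estimated correlation), but not without AKR 1 (adjusted p = 0.253) or SAMP 1 (adjusted p = 0.0593).

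**Figure D4:**
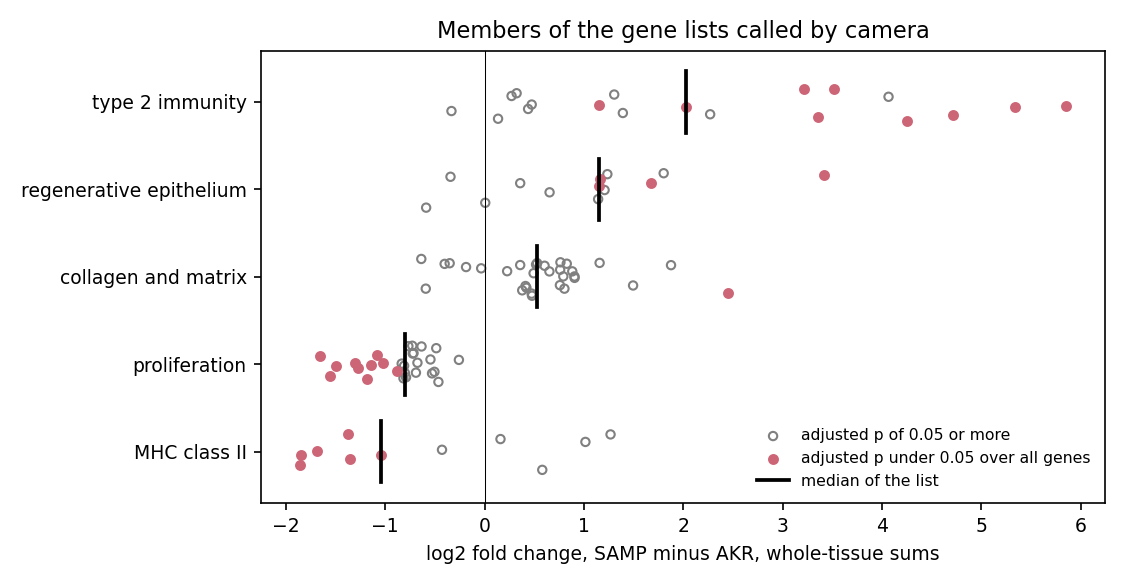
Log2 fold change (SAMP minus AKR, whole-tissue sums) of each measured member of the 5 lists that passed camera; filled points passed an adjusted p of 0.05 over all genes, open points did not, and bars mark list medians. The medians run from -1.05 for MHC class II to 2.03 for type 2 immunity.

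Among the lists of epithelial function that did not pass camera, members moved apart. In the goblet and mucin list 3 of 20 members were higher and 6 lower, the same adjusted over the list alone. The lower ones included Zg16, a lectin of the mucus layer (618 ± 208 CPM against 4538 ± 208; log2 -2.88 ± 0.34), Agr2, a mucin-folding disulfide isomerase (log2 -2.24 ± 0.22), and the trefoil peptide Tff3 (log2 -1.94 ± 0.34). The median of this list was 0.26, its mean -0.13 and its direction in camera downward (adjusted p = 0.422). Of 25 Paneth products, 8 were higher and 8 lower, with 8 and 9 adjusted over the list alone. The lipase-like Pnliprp2 was at log2 5.27 ± 0.29 and the defensin Defa23 at -5.93 ± 0.49, with a list median of 0.44 and mean of -0.26 (camera adjusted p = 0.543). Epithelial defence had 5 of 19 members higher and 5 lower (5 and 6 adjusted over the list alone), with the ribonuclease Ang4 at log2 4.01 ± 0.38, the lectins Reg4 at 3.57 ± 0.53 and Reg1 at -3.33 ± 0.50, and the oxidase Duox2 at 1.55 ± 0.27. In bile acid handling 1 of 9 members was higher and 3 lower, the same adjusted over the list alone: Slc51b, a subunit of the basolateral bile acid exporter, was at log2 -2.20 ± 0.36 and Abcc3 at -1.30 ± 0.22, while Fabp6 (-2.07 ± 0.50) and Fgf15 (2.57 ± 0.67) lost their calls without AKR 2 (adjusted p = 0.0630 and 0.0626). Lipid absorption had 1 of 21 members higher and 5 lower (1 and 6 adjusted over the list alone), with Fabp2, the intestinal fatty acid binding protein, at log2 -2.16 ± 0.40, Abcg8, a sterol exporter, at -2.20 ± 0.35 and Acadm at -1.28 ± 0.19.

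Smaller counts were found in the remaining epithelial lists. Sugar and peptide absorption had 1 of 19 members lower (0 adjusted over the list alone), the glucosidase Mgam at log2 -1.45 ± 0.40, a call lost without AKR 1 (adjusted p = 0.139), SAMP 1 (0.0817), SAMP 2 (0.0624) or SAMP 3 (0.0631). The villus tip list had 1 of 9 members higher, Enpp3 at log2 2.11 ± 0.53, with 1 adjusted over the list alone and the call lost without AKR 2 (adjusted p = 0.0876). The crypt stem list had 3 of 17 members higher and 1 lower (3 and 0 adjusted over the list alone). Sox9 (1.27 ± 0.19) and Prom1 (1.39 ± 0.21) lost their calls with equal class makeup. The unfolded protein response list had 2 of 18 members lower, the same adjusted over the list alone, with the chaperone cofactor Sdf2l1 at log2 -2.53 ± 0.38. Circadian clock genes were higher for 3 of 15 and lower for 1 (2 and 1 adjusted over the list alone), and none of these 4 kept its call without AKR 1 (adjusted p = 0.0932 to 0.298). Handling stress genes were higher for 2 of 15 and lower for 1, the same adjusted over the list alone, and none of these 3 kept its call without AKR 1 (adjusted p = 0.0760 to 0.167).

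The immune and stromal lists other than those above did not pass camera in whole tissue. The interferon response list had 1 of 38 members higher and 8 lower, the same adjusted over the list alone, with the chemokine Cxcl9 at log2 -2.57 ± 0.37 and the immunoproteasome subunit Psmb8 at -1.97 ± 0.32. In type 1 and 17 immunity 3 of 12 members were lower, the same adjusted over the list alone: Cxcl9, Cxcl10 (log2 -2.90 ± 0.52) and Cxcr3. Cxcr3 lost its call with DESeq2 (adjusted p = 0.0592) and with thinning to the smallest library (0.0878). It also lost it without SAMP 1, SAMP 2 or SAMP 4 (0.0636 to 0.0677), without AKR 1 (log2 -1.68) and without AKR 2 (log2 -1.64). The lymphoid follicle list had 2 of 20 members higher and 1 lower, the same adjusted over the list alone: Tnfsf13b, the B cell survival factor BAFF, was at log2 2.36 ± 0.40, and Ccl21a, a chemokine of lymphatic vessels, had 0 counts in SAMP and was at least 123-fold higher in AKR, taking a floor of 3 counts over the strain's libraries. SAMP 1 to SAMP 4 held 28, 39, 54 and 22 lymphatic endothelial nuclei, so 0 counts need not be a loss of expression. An effect of strain sequence on the mapping of Ccl21a to mm10 was not tested. Lymphatic growth had 5 of 15 members higher and 2 lower, the same adjusted over the list alone. Prox1, the master regulator of lymphatic identity, was at log2 1.85 ± 0.21, Adm at 2.30 ± 0.33 and Angpt2 at -1.34 ± 0.28. Prox1 had 1035 counts in AKR, where AKR 1 and AKR 2 held 4 and 9 lymphatic endothelial nuclei. Its difference is therefore no measure of lymphatic nuclei alone. With equal class makeup, which leaves out lymphatic endothelial, tuft and enteroendocrine nuclei, Prox1 was at -0.24, where the median gene was at -0.38. The list median was 0.44 and its mean -0.03. Muscle contraction had 6 of 21 members higher, the same adjusted over the list alone, with the calcium channel Cacna1c at log2 1.30 ± 0.20 and Synpo2 at 0.98 ± 0.18, which were at -0.44 and -0.47 with equal class makeup, close to the shift of -0.38 of the median gene there. Synthetic muscle had 1 of 13 higher, Fn1, and 1 lower, the calcification inhibitor Mgp (log2 -2.44 ± 0.48). Stromal niche signals had 3 of 16 higher and 1 lower, Wnt2b (log2 -2.32 ± 0.36), each list the same adjusted over the list alone. The 3 higher ones, Wnt5b, Dkk2 and Bmp2, lost their calls without AKR 1 (adjusted p = 0.117 to 0.163) and without AKR 2 (adjusted p = 0.0653 to 0.128). Enteric transmitters had 3 of 13 higher, among them Chat, which makes acetylcholine also in tuft cells (log2 5.09 ± 1.09). Reactive glia had 2 of 9 lower, among them Cxcl10, and inflammatory stroma had 1 of 14 higher, these 3 lists the same adjusted over the list alone. That 1 gene, the decoy receptor Il13ra2, had 0 counts in AKR and was at least 10.7-fold higher in SAMP by the same floor, with its call lost without AKR 1 (adjusted p = 0.0505). The gastric gland list had fewer than 3 measured members and was not tested. With the file name prefix as a block, the list members named in whole tissue that kept their calls were Fn1, Ccr3, Retnla, Retnlb, Ang4, Reg4, Pnliprp2, Defa23, Slc51b, Abcg8, Tnfsf13b and Prox1. Others lost their calls at differences of about the same size, for example Il1rl1 at log2 4.64, Cd74 at -1.72 and Synpo2 at 1.11, so a lost call there is no evidence of a prefix effect.

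Within enterocytes, the sialyltransferase gene St3gal4 and the galactosaminyltransferase gene Galnt14 were among the most raised in SAMP, and ribosomal protein genes held a smaller share of UMIs. St3gal4 was at 647 ± 357 CPM in SAMP and 0.457 ± 0.240 in AKR (log2 10.45 ± 0.89). The proprotein convertase Pcsk6 was at log2 9.81 ± 1.01, Galnt14 at 8.38 ± 0.73 and Ppef1 at 8.33 ± 0.39. The nucleoside diphosphate kinase Nme2 was at log2 -4.70 ± 0.49, the ATP synthase subunit Atp5g1 at -3.80 ± 0.39 and Oat at -3.72 ± 0.47. The ribosomal proteins Rpl13 and Rps23 were at -3.42 ± 0.51 and -3.41 ± 0.48. Together 97 ribosomal protein genes held 0.211%, 0.119%, 0.160% and 0.351% of enterocyte UMIs in SAMP 1 to SAMP 4 and 0.980% and 1.35% in AKR 1 and AKR 2. The unnamed SAMP epithelial clusters were not part of this comparison. Enterocytes of the strains came from almost wholly separate clusters, so a different mix of enterocytes cannot be told apart from changes within them. In all, 2814 of 15481 genes passed (edgeR quasi-likelihood, Benjamini-Hochberg), 1507 higher and 1307 lower, and 1520 passed with the file prefix as a block, 1346 of them shared. Only 6 genes passed without AKR 1, 198 without AKR 2, 607 without SAMP 1 and 1249 without SAMP 3. Of the 9 genes named here, Ppef1 alone kept its call without AKR 1.

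Enterocyte MHC class II genes were lower for 4 of 9 members and 6 adjusted over the list alone (camera adjusted p = 0.000390; adjusted p = 0.776 with an estimated correlation), with Cd74 at 91.5 ± 42.0 CPM against 515 ± 21.8. Villus tip genes were higher for 2 of 9 and 5 adjusted over the list alone, Enpp3 (log2 2.83 ± 0.59) and the nucleoside transporter Slc28a2 (log2 1.44 ± 0.35), and passed camera upward (adjusted p = 0.0107; adjusted p = 0.776 with an estimated correlation). A cluster with Nt5e, Slc28a2 and Enpp3 among its top genes held 17.2% of SAMP and 0.120% of AKR enterocytes. The proliferation list passed camera downward with 0 of 28 members called over all genes and 0 adjusted over the list alone (adjusted p = 0.00769; adjusted p = 0.776 with an estimated correlation), and not without AKR 2 (adjusted p = 0.230). The other enterocyte lists did not pass: interferon response had 2 higher and 4 lower of 38, epithelial defence 1 higher and 2 lower of 19, bile acid handling 1 higher and 3 lower of 9, and lipid absorption 1 higher and 3 lower of 21. The circadian clock had 2 higher of 14, regenerative epithelium 1 higher of 12, and sugar and peptide absorption and handling stress 0 of 19 and 0 of 13. Of each list's up to 4 members with the smallest p, all those called in enterocytes lost their calls without AKR 1, for example Cd74 (adjusted p = 0.101) and Enpp3 (adjusted p = 0.104).

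In goblet nuclei of SAMP, Pnliprp2 and Ang4 were higher and 7 members of the goblet and mucin list lower. Pnliprp2 was at 450 ± 186 CPM in SAMP and 0.883 ± 0.0951 in AKR (log2 8.90 ± 0.69), Ang4 at 1346 ± 478 against 8.83 ± 4.99 (log2 7.21 ± 0.55), with Ppef1 and Pla2g4c also higher, at log2 7.60 ± 0.35 and 6.93 ± 0.40. The sulfotransferase Hs3st5 was at log2 -5.03 ± 0.78, Nme2 at -4.43 ± 0.30, Atp5g1 at -3.72 ± 0.38, Oat at -3.55 ± 0.64 and Def8 at -3.53 ± 0.18. The goblet and mucin list had 1 of 19 members higher and 7 lower (1 and 8 adjusted over the list alone) and passed camera downward (adjusted p = 0.00221; adjusted p = 0.332 with an estimated correlation): Zg16 was at 8145 ± 3383 CPM against 61350 ± 14960, Agr2 at log2 -2.94 ± 0.26 and St6galnac1, a mucin sialyltransferase, at -3.05 ± 0.14. Sdf2l1 was at log2 -3.69 ± 0.52. Hspa5, also lower, lost its call without SAMP 3 (edgeR adjusted p = 0.0513), AKR 1 (log2 -1.265) or AKR 2 (log2 -1.071). The unfolded protein response list, which holds both, had 5 of 17 members lower, the same adjusted over the list alone. It passed camera (adjusted p = 0.0428; adjusted p = 0.340 with an estimated correlation), but not without AKR 1 (0.0668), AKR 2 (0.0522), SAMP 2 (0.0577) or SAMP 4 (0.143). Of 10390 genes, 2911 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 1518 higher and 1393 lower, with 2286 under the file prefix block, 680 without AKR 1 and 805 without AKR 2. SAMP goblet nuclei came almost wholly from a cluster that held 28.3% of the AKR ones.

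In Paneth nuclei, transcripts of the gasdermins Gsdmc4 and Gsdmc3 were counted in SAMP but not in AKR, and several defensins were far lower in SAMP. Gsdmc2 was higher in 7 of 11 classes, and how much of the gasdermin counts in Paneth nuclei is free RNA was not measured. The unnamed AKR cluster led by Defa21 was not part of this comparison. Gsdmc4, a pore-forming protein, was at 243 ± 87.1 CPM in SAMP and had 0 counts in AKR, at least 74.8-fold higher by the floor of 3 counts over the AKR libraries. Gsdmc3 was at least 53.8-fold and the nucleoside transporter Slc28a1 at least 20.5-fold higher. Gsdmc2 was at 436 ± 159 CPM against 0.845 ± 1.19, and Pla2g4c at 1100 ± 376 against 2.53 ± 3.58, from 1 and 3 AKR counts. Defa21 was at 3.77 ± 0.646 CPM against 3827 ± 380 and Defa22 at 52.8 ± 23.2 against 3191 ± 55.5 (log2 -5.91 ± 0.44). Defa36 was at log2 -6.72 ± 0.58, the repressor Klf12 at -6.00 ± 0.24 and the sialyltransferase St3gal1 at -5.04 ± 0.61. Of 12041 genes, 1908 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 849 higher and 1059 lower, but 0 with the file prefix as a block, where these 10 genes had adjusted p from 0.0758 to 0.149. Their differences stayed about as large there, for example Klf12 at log2 -5.96 and Defa22 at -5.53, so the lost calls are no evidence of a prefix effect. The count was 705 without AKR 1, 1196 without SAMP 1, 1044 without SAMP 3 and 1120 without SAMP 4, and the 10 named genes kept their calls in each.

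In crypt progenitors, counts of the same gasdermin and transferase genes were higher, and how much of them is free RNA was not measured. Galnt14 was at 67.6 ± 36.6 CPM in SAMP with 0 counts in AKR, at least 156-fold higher. St3gal4 was at log2 7.62 ± 0.65, Gsdmc4 and Gsdmc3 at 7.41 ± 0.64 and 7.38 ± 0.74, and the regulator Trerf1 at 7.06 ± 0.55. The bile acid receptor paralog Nr1h5 was at log2 -6.46 ± 0.88, Klf12 at -5.86 ± 0.48, Def8 at -3.81 ± 0.40, Clca3a2 at -3.63 ± 0.23 and Pard3bos1 at -3.30 ± 0.20. The proliferation list passed camera downward (adjusted p = 0.00334; adjusted p = 0.758 with an estimated correlation), with 1 of 28 members lower and 2 adjusted over the list alone, though not without AKR 1 (adjusted p = 0.151). The class pools cycling and Lgr5 clusters in a different mix, the cycling one holding 59.95% of AKR and 46.9% of SAMP nuclei of the class. Paneth products had 2 higher and 5 lower of 20, and crypt stem 1 higher and 1 lower of 17. Epithelial defence had 1 higher of 14, and regenerative epithelium and the unfolded protein response 0 of 4 and 0 of 15. The crypt stem gene Lrig1 lost its call without any 1 SAMP library (adjusted p = 0.0613 to 0.121). Tnfrsf19 lost it without SAMP 1, SAMP 3 or SAMP 4 (0.0531 to 0.0838), and Reg4 without SAMP 2 or SAMP 3 (0.0581 and 0.0773). Lrig1, Tnfrsf19 and Reg4 also lost their calls without AKR 1 (log2 0.51, -1.37 and 2.59) and without AKR 2 (log2 0.84, -1.08 and 3.55). Of 11418 genes, 655 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 283 higher and 372 lower, and 1723 under the file prefix block. Without AKR 1 the count was 36, without AKR 2 19, without SAMP 2 285 and without SAMP 3 144. Galnt14, Gsdmc3 and Gsdmc4 lost their calls without AKR 1 and without AKR 2 (adjusted p = 0.0517 to 0.0911). So did Nr1h5 (0.0750 and 0.0862, and 0.142 with DESeq2), while Def8 lost its call without AKR 1 (0.0724) and St3gal4 without AKR 2 (0.0517). Klf12, Clca3a2, Pard3bos1 and Trerf1 kept their calls in each of these.

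In smooth muscle nuclei of SAMP more genes were lower than higher, among them the calcification inhibitor Mgp. Mgp was at 11.3 ± 3.64 CPM in SAMP and 219 ± 77.3 in AKR (log2 -4.20 ± 0.34). The scaffold Sntg1 was at log2 -5.58 ± 0.73, Pard3bos1 at -3.84 ± 0.43, the selenoprotein Selenom at -3.72 ± 0.30 and Atp5g1 at -3.56 ± 0.23. Higher were Gsdmc3, with 0 counts in AKR and at least 28.6-fold higher in SAMP, Pla2g4c (log2 8.34 ± 0.75), Frmd5 (155 ± 90.0 CPM against 0.628 ± 0.888) and Slc28a1 (116 ± 33.7 CPM against 1.26 ± 1.78). The mix of smooth muscle clusters differed between the strains: a cluster led by Des, Synm and Cnn1 held 23.1% of AKR and 10.3% of SAMP nuclei of the class, and a cluster led by Lmod1, Myh11 and Acta2 5.28% and 23.55%. The muscle contraction list had 0 of 21 members called, with the actin-binding Tagln at 365.5 ± 175 CPM against 986 ± 546. Synthetic muscle had 1 of 10 lower (2 adjusted over the list alone), and neither list passed camera (adjusted p = 0.0514 for both). Collagen and matrix had 0 of 23 called and circadian clock 1 lower of 15, Nr1d1, which lost its call without any 1 of the libraries except SAMP 4 (adjusted p = 0.0653 to 0.332). Frmd5 lost its call without AKR 1, AKR 2, SAMP 2 or SAMP 3 (adjusted p = 0.0531 to 0.108), and Sntg1 without AKR 1 or SAMP 2 (adjusted p = 0.0622 and 0.0523). With a uniform doublet share Slc28a1 lost its call and was at log2 3.64 (adjusted p = 0.0612). Of 10672 genes, 494 passed (edgeR quasi-likelihood, Benjamini-Hochberg), 91 higher and 403 lower, with 1072 under the file prefix block. The count was 48 without AKR 1, 107 without AKR 2, 72 without SAMP 2 and 191 without SAMP 3. RNA of enterocyte marker genes in SAMP smooth muscle nuclei stood at 40.1% of its epithelial level, so free RNA is not excluded as a source of the Gsdmc3 and Pla2g4c counts there.

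Few genes passed in the remaining stromal and immune classes. In fibroblasts 8 of 9246 genes were higher and 18 lower (edgeR quasi-likelihood, Benjamini-Hochberg): Dok6, a receptor tyrosine kinase adaptor, was at log2 -7.52 ± 0.56, the substance P receptor Tacr1 at -3.41 ± 0.37, Adamts18 at -3.12 ± 0.36 and the lipoprotein Apoe at -2.94 ± 0.34, while the protocadherin Pcdh9 was at 5.65 ± 0.61. H2-Eb1 was at -2.67 ± 0.37, and Gsdmc2 and Gsdmc4 at 5.75 ± 0.59 and 6.43 ± 0.67, from 3 and 1 AKR counts. Gsdmc3 had 0 counts in AKR and was at least 16.5-fold higher by the floor of 3 counts. The interferon response list passed camera downward in fibroblasts (adjusted p = 4.03e-10; adjusted p = 0.253 with an estimated correlation) with 0 of 30 members called and 9 lower adjusted over the list alone, for example Gbp7 at 24.9 ± 9.19 CPM against 126 ± 4.41. Collagen and matrix (28 measured), inflammatory stroma (6), stromal niche signals (14), handling stress (8) and circadian clock (13) had 0 members called and did not pass. In blood endothelial nuclei 11 of 8744 genes were higher and 32 lower, with Dok6 at 0.262 ± 0.524 CPM against 110.5 ± 21.4 and the interferon-induced Ifitm2 at log2 -3.53 ± 0.52. Def8 was at -3.30 ± 0.36, and the globin gene Hbb-bs and the myeloid gene Fcer1g, markers of other cell types, at -4.80 ± 0.59 and -3.06 ± 0.49. The epithelial genes Gsdmc2, Slc28a1, Defa27 and Sprr2a3 were higher there, at log2 6.66 ± 1.11, 5.53 ± 0.92, 4.99 ± 0.80 and 3.40 ± 0.53. Gsdmc2, Slc28a1 and Defa27 had 1, 1 and 2 AKR counts there, so the size of their differences is uncertain. In both classes Pla2g4c was higher (log2 6.92 ± 0.50 and 6.11 ± 0.69), and enterocyte marker RNA stood at 27.0% and 23.1% of its epithelial level. Counts ranged without single libraries from 2 without SAMP 2 or SAMP 3 to 52 without AKR 2 in fibroblasts (16 without AKR 1, 10 without SAMP 1 and 6 without SAMP 4), where Pla2g4c alone among the named genes kept its call each time. In endothelial nuclei they were 0 without AKR 2 or SAMP 3, 1 without SAMP 2 or SAMP 4, 86 without SAMP 1 and 254 without AKR 1. The file prefix block gave 48 and 49.

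In macrophage or dendritic nuclei MHC class II and interferon genes were lower as sets, and these were the 2 list results that held with an estimated correlation. MHC class II passed downward (camera adjusted p = 8.02e-10; adjusted p = 0.00893 with an estimated correlation) with 0 of 9 members called and 5 lower adjusted over the list alone. H2-Aa was at 404 ± 54.5 CPM in SAMP and 965 ± 11.8 in AKR. Interferon response passed downward (adjusted p = 1.76e-07; adjusted p = 0.00893 with an estimated correlation) with 0 of 20 members called and 3 lower adjusted over the list alone, among them the GTPase Iigp1 at 18.3 ± 9.90 CPM against 96.4 ± 10.3. MHC class II genes were also lower in enterocytes, and how much of the counts of these 2 lists is free RNA was not measured. The mix of macrophages and dendritic cells was not compared between the strains in this class. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 3 of 7329 genes there: Pla2g4c was higher (log2 5.80 ± 0.50; at 30.6% of its epithelial level, against 20.3% for enterocyte marker RNA), and Def8 (-4.74 ± 0.46) and Gm26740 (-7.98 ± 0.55) were lower. In T or innate lymphoid nuclei it called 4 of 8173: the ubiquitin-conjugating enzyme Ube2e2 was higher (2.59 ± 0.26), and Def8 (-3.75 ± 0.33), Gm26740 (-9.57 ± 0.41) and Gm44175 (-4.02 ± 0.36) were lower. In B nuclei it called 1 of 8698, Gm26740, at 0.190 ± 0.380 CPM against 665 ± 102. Gm26740 and Gm44175 were chosen after their values were seen. Ube2e2 lost its call without any 1 library (adjusted p = 0.116 to 0.381), with RLE size factors (0.0503) and with scaled clustering (0.111), and Def8 in T or innate lymphoid nuclei without any library except AKR 2 (0.0593 to 0.168). In macrophage or dendritic nuclei Pla2g4c lost its call without AKR 2 or SAMP 2 (0.0528 and 0.0521), and Def8 without AKR 2, SAMP 2 or SAMP 3 (0.0712 to 0.148). The number of called genes was 1 without SAMP 2 or SAMP 3 and 11 without AKR 1 for macrophage or dendritic nuclei. For T or innate lymphoid nuclei it was 2 without AKR 1, 7 without AKR 2, 0 without SAMP 3 and 1 without SAMP 1, SAMP 2 or SAMP 4. For B nuclei it was 1 without SAMP 3 but 0 without any other library. With the file prefix block it was 11, 0 and 0.

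The type 2 list passed camera upward in T or innate lymphoid nuclei (adjusted p = 0.0285; adjusted p = 0.206 with an estimated correlation), with 0 of 6 members called and 2 higher adjusted over the list alone. Il1rl1 was at 132 ± 106 CPM against 3.37 ± 4.76 and Gata3, the type 2 lineage factor, at 154.5 ± 70.8 against 43.3 ± 1.68. In SAMP this class held 313 of the 10408 Il1rl1 counts of whole tissue, so most of that gene's whole-tissue counts lay elsewhere. How much of its counts in this class is free RNA was not measured. The strains differed here in the mix of cells, since the cluster led by Cd8a held 75.8% of AKR but 27.15% of SAMP nuclei of the class, and the list counts the goblet marker Clca1 among its members. Type 1 and 17 immunity had 0 of 7 members called there and did not pass. In B nuclei MHC class II passed downward (adjusted p = 0.00272; adjusted p = 0.395 with an estimated correlation) with 0 of 11 members called and 0 adjusted over the list alone, and not without AKR 1 (adjusted p = 0.967), while lymphoid follicle had 0 of 13 called and did not pass. Plasma nuclei gave 0 of 2140 genes in the edgeR quasi-likelihood test, 91 at an unadjusted p under 0.05 and 9 with DESeq2, and 0 of 8 members of the unfolded protein response list.

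Sex was balanced within the strains, and the genes that separated the sexes were those of the sex chromosomes. Xist, the RNA that silences an X chromosome, was at 1207 ± 203 CPM in the 3 female libraries and 0.462 ± 0.198 in the 3 male ones, and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in males, by log2 values of -10.03, -11.31, -9.06 and -9.48 (female minus male). With Tsix, these made up the 6 genes called (edgeR quasi-likelihood, Benjamini-Hochberg), 2 higher and 4 lower in females, and each library's sex label fitted them. The strain by sex interaction, which rests on 1 female and 1 male AKR library, was called for 11 genes, all with a larger strain difference in females: Dclk1, Rgs13, Sh2d7, Chat, Itprid1, Dgki, Nrg1, Rgs22, Stxbp5l, Adgrg4 and Gm26871, of which Dclk1 and Rgs13 are tuft cell markers. Dclk1 was at 630 and 617 CPM in the female and 427 and 326 in the male SAMP libraries, and at 0.894 in the female and 32.3 in the male AKR library, with an interaction of log2 5.90 ± 0.50. With doublets kept or a uniform doublet share 0 of the 11 genes passed, and their median interaction went from log2 5.88 to 1.19 and 1.23.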

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

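The tests of the Gm42418 share and, for tuft nuclei, those of doublet removal and of fewer enterocytes were chosen only after the result was seen.

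For 15 of 351 groups of 4 SAMP libraries, 1 library lay far from the other 3; chance flags about 1 in 20 groups, so this number is no more than chance gives. In whole tissue these were Defa36 at 1.20 CPM in SAMP 4, Il11 at 1.08, Ccr3 at 3.64, Bcl6 at 68.5, Defa23 at 0, Xbp1 at 26.5 and Tef at 93.3 CPM in SAMP 2, and Fgf15 at 218.4 CPM in SAMP 1. In crypt progenitors they were Nr1h5 at 4.5 and Defa21 at 8.36 CPM in SAMP 2, Reg4 at 114.2 in SAMP 1, Defa36 at 0.488 in SAMP 4 and Sel1l at 131 in SAMP 3. The others were Dok6 at 1.05 CPM in blood endothelial nuclei of SAMP 3 and Nr1d1 at 10.2 CPM in enterocytes of SAMP 2. No explanation of these was tested.

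The strain difference differed between females and males for 11 genes in the interaction test (edgeR quasi-likelihood, Benjamini-Hochberg): Rgs13 (log2 4.09), Dclk1 (5.90), Gm26871 (5.33), Dgki (4.56), Itprid1 (11.40), Nrg1 (4.19), Sh2d7 (5.88), Chat (10.22), Rgs22 (6.96), Stxbp5l (6.33) and Adgrg4 (5.20). Itprid1 and Chat had 0 CPM in AKR 1, so their values are fitted over a count of 0 and are not sizes. AKR has 1 female and 1 male library, so the interaction rests on AKR 1 against AKR 2. Doublet removal in the AKR female is a candidate explanation: AKR 1 lost 23.8% of its nuclei as doublets and held no tuft nucleus afterwards. With doublets kept, 0 of the 11 genes were still called and their median interaction went from 5.88 to 1.19, as the explanation predicted before the test was run; with a uniform doublet share it was 1.23 and 0 were called. A difference between the sexes in the strain effect is not excluded by this and was not tested further.

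Barcodes with at least 500 UMIs but under 300 genes, which the comparisons did not use, numbered 3152, 2791 and 1855 in SAMP 1, SAMP 2 and SAMP 3, against 61 and 0 in AKR 1 and AKR 2 and 1 in SAMP 4. The ribosomal RNA-like Gm42418 held 18.5% to 22.4% of UMIs in the SAMP libraries and 2.09% and 3.14% in the AKR libraries. A batch that follows the file prefix is argued against, since within the 2 prefixes with both strains the SAMP share was at least 5.90 times the AKR share. Free RNA spread alike over all droplets is argued against as well, since the median Gm42418 UMIs of the highest class were at least 3.17 times those of the lowest class in each SAMP library. A difference in sequence or copy number between the strains would raise the share in every class, and the lowest ratio over the tested classes was 4.97; this cannot be told apart from another difference that follows strain, because strain and handling by strain are confounded here.

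More tuft nuclei in SAMP ileum were weighed against 3 technical explanations. Doublet removal is argued against, since with doublets kept the SAMP mean was 25.2 times the AKR mean. Depth and clustering are argued against, since at 1000 UMIs per nucleus, without clustering and with doublets kept, the ratio of means was 19.4. A lower share of enterocytes would raise the other classes alike, but the lowest ratio among these was 0.735. A larger number of tuft cells in SAMP ileum may therefore be the explanation, as a hypothesis from the same data; a strain difference in how well these nuclei survive isolation was not tested.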

How the results depend on the processing

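The uniform doublet share, the removal of ribosomal RNA-like genes, the UMI minimum without them, the unnamed clusters counted as enterocytes or Paneth nuclei and, for sex, the doublets kept were chosen only after the result was seen. Unless stated, the cause of a change was not tested. When a strain or sex is left with 1 library, that library is assumed to vary like the others.

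The whole-tissue count of 5314 stayed within 1.5 times under every setting except equal class makeup (8271), the file prefix block (488), the replicate block (3480) and leaving out AKR 1. Leaving out 1 library gave 2817 to 4800 genes in whole tissue, 6 to 3468 in enterocytes, 680 to 2920 in goblet, 705 to 2633 in Paneth, 19 to 690 in crypt, 48 to 474 in smooth muscle, 0 to 254 in blood endothelial, 2 to 52 in fibroblast, 0 to 7 in T or innate lymphoid, 1 to 11 in macrophage or dendritic, 0 to 1 in B and 0 to 4 in plasma nuclei, 4 to 7 sex genes, 3 to 10 whole-tissue lists and 9 to 15 class lists. Differences in share ranged from -0.131 to 0.301 for enteric neuron or glia, -0.0936 to 0.868 for macrophage or dendritic, 4.08 to 4.77 for tuft, 7.27 to 8.03 for Paneth and -28.7 to -21.1 for enterocytes.

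The replicate block gave 419 genes in B, 0 in Paneth, 0 in endothelial, 2 in crypt, 1422 in enterocytes, 0 in fibroblast, 1603 in goblet, 25 in macrophage or dendritic and 1 in smooth muscle nuclei, and 8 lists. This block joined libraries of the same sex and number within sex, AKR 1 with SAMP 1 and AKR 2 with SAMP 3. Their deviations correlated at 0.1185 and 0.3032. The libraries that share a file prefix were at -0.3032 and -0.02592. With 2 AKR libraries, the deviations of AKR 1 and AKR 2 mirror each other. These correlations therefore cannot show whether libraries of a block or prefix share a batch. The file prefix block gave 0 in B, 0 in Paneth, 0 in T, 1723 in crypt, 1520 in enterocytes, 48 in fibroblast, 11 in macrophage or dendritic and 1072 in smooth muscle nuclei.

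DESeq2 gave 55 in B, 99 in T, 115 in endothelial, 4381 in enterocytes, 140 in fibroblast, 56 in macrophage or dendritic, 9 in plasma and 1135 in smooth muscle nuclei, 67 for sex and 165 for strain by sex. Without a low-count filter there were 6 in B, 39 in T, 618 in endothelial, 1361 in crypt, 459 in fibroblast, 297 in macrophage or dendritic, 33 in plasma and 1023 in smooth muscle nuclei, 30 for sex and 487 for strain by sex. RLE size factors gave 3 in B and 41 in fibroblast nuclei. Sex as a covariate gave 39 in B, 25 in T, 77 in endothelial, 287 in crypt, 3 in fibroblast, 10 in macrophage or dendritic and 2 in plasma nuclei.

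With doublets kept there were 283 in B, 349 in T, 734 in endothelial, 1016 in crypt, 492 in fibroblast, 402 in macrophage or dendritic, 15 in plasma and 1797 in smooth muscle nuclei, and 0 for strain by sex. A uniform doublet share gave 6 in B, 14 in T, 468 in endothelial, 67 in fibroblast, 55 in macrophage or dendritic and 1 in plasma nuclei, and 0 for strain by sex. Leaving out ribosomal RNA-like genes gave 3 in B nuclei. Scaled clustering gave 3 in B, 2 in T, 129 in endothelial, 2 in fibroblast, 6 in macrophage or dendritic and 951 in smooth muscle nuclei; for Paneth nuclei it gave 1792, of which 362 were shared. Leaving out genes low against their highest class gave 4 in B, 14 in T, 73 in endothelial, 41 in fibroblast and 8 in macrophage or dendritic nuclei.

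The edgeR test of nuclei counts passed for Paneth (2.50), lymphatic endothelial (2.45) and tuft nuclei (5.27), which the exact test cannot; with the unnamed defensin cluster counted as Paneth nuclei, their share difference was 1.49 and did not pass. An estimated correlation left 0 lists in whole tissue and 2 in classes, fry gave 2 and 5 in one direction and 22 and 22 in either. Among lists without a call, direction switched for 11 without AKR 1, 5 without AKR 2, 1, 3, 2 and 4 without SAMP 1 to SAMP 4, 6 with the replicate block, 1 with the sex covariate and 1 without ribosomal RNA-like genes.

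Some differences changed sign. The goblet share difference was 2.90 with scaled clustering and 0.613 with its own compartment as denominator, that of interstitial cells of Cajal -0.0129 with doublets kept and -0.00749 with a uniform doublet share, and those of macrophage or dendritic and plasma nuclei -0.0633 and -0.193 with their own compartment. With equal class makeup Cacna1c was at -0.44, Msi1 at -0.22, Myocd at -0.26 and Nmu at -0.052. Prox1 was at -0.24, Synpo2 at -0.47 and Wnt5b at -0.30. The median gene was at -0.38 there, so these signs follow a shift of most genes. Nuclei outside the tested classes, lymphatic endothelial nuclei among them, were also left out there.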

Other observations

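No test in this part was chosen only after its result was seen.

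Of the genes called in the same direction in at least 4 classes, 85 were higher and 135 lower in SAMP; Pla2g4c was higher in 8 of 11 classes and Gsdmc2 in 7. Free epithelial RNA is a candidate explanation for those also called higher in a non-epithelial class, which were 44 genes in smooth muscle, 10 in blood endothelial, 7 in fibroblast and 1 in macrophage or dendritic nuclei and 0 in B, T or innate lymphoid and plasma nuclei. In the 4 classes with such genes they stood, relative to their epithelial level, at a median of 1.67 times the level of enterocyte marker genes, within the limit of 3 times that was set before the test. The ratios of these 4 classes ran from 1.33 to 2.13, so some expression of these genes in the classes themselves is not excluded.

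The 6 sex genes came from 1 of 10 splits of the 6 libraries into 3 and 3, the real one, and the highest of the other splits gave 0 genes; 10 splits are too few for a share under 0.05.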
